A study of Schizosaccharomyces pombe with 4 samples.

How the data were processed

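Messenger RNA was profiled in 2 groups of fission yeast, wild type and red2 deletion, with 2 arrays per group. Per the labels' protocols, cultures grew logarithmically in rich medium with glucose and adenine, total RNA was extracted with the mirVana kit, and labelling with Cy3 was done by the array's maker, NimbleGen. Replicates were grouped by sample title. One label of deletion replicate 2 names red3 in place of red2, and the array was kept in the red2 deletion group because its other labels say so.

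The values are linear intensity values that the authors deposited after RMA, per the submitters' processing notes, which give no version. RMA in general corrects background, equalises the distributions of arrays and summarises probes, and which of these steps were run is not given in the sources used here. The authors deposited 1 table of all 4 arrays and 2 tables that pair a wild-type with a deletion array, and all 9994 values of each array were exactly equal in both. The pair tables also hold the authors' deposited ratio of deletion to wild type, which equalled the quotient of the intensity columns on all 9994 lines of each to within 1e-06. Each gene has 2 blocks of values on an array. What the blocks stand for is not given in the sources used here. They differed by a median of 0.09 to 0.10 on the log2 scale within an array and were averaged there. Intensities ran up to 65027.6, near the top of the scale, where differences are compressed. The share of mismatch probes in the values and any call of signal over background are not given in the sources used here, so no fold is quoted against a group at the floor of the scale.

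Array genes carry a free-text description, a chromosome and a start and end, and those coordinates are printed as deposited; the build is not named in the sources used here. Gene symbols were taken from the description where a word in it matched a symbol or synonym of the reference table (assembly ASM294v3) on the same chromosome, and where its offset to the reference lay within 10 kb of that of at least 2 of its nearest matched genes. This gave a symbol to 244 of the 4997 array genes, with 238 distinct symbols, and 27 matches were dropped. No coordinate of the reference table was used otherwise. Of all array genes, 1827 are described as hypothetical or have no description, and these can include genes with a symbol. Gene length is the span from start to end and so holds introns.

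The main test was limma (version 3.58.1, R 4.3.3; lmFit and eBayes) on log2 values of all 4 arrays with genotype as the only term, two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Errors given after ± are limma's standard errors of the log2 fold change. No pseudocount, filter or further normalization was applied. Counts of genes at least 2-fold apart whose groups do not overlap are a description and no test. Gene list shifts were tested with camera at a preset correlation of 0.01, against camera with an estimated correlation and fry. With 4 arrays, camera with an estimated correlation has few residual degrees of freedom, so few lists could pass it whatever their correlation. Of 26 gene lists fixed before the data were examined, 7 had at least 3 members with a symbol and were tested as 1 family; the other 19 were not. Because of that, 27 further groups were formed from words in the descriptions or from position, after the annotation was read and before fold changes were computed, and tested as another family. The word for the Tf2 elements was later narrowed, since it also took a nuclear transport factor.

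The genes named in the text were chosen by a rule fixed before the data were examined: in each direction the 12 with the largest change among those past the threshold with no overlap between groups, up to 4 members of each list with the smallest p, and a fixed set of meiotic and RNA elimination genes. Of the features of unknown function in those 12, the lost gene and the UPF0057 gene are named by position. Members of the description groups were taken as their extremes, after their values were seen, as were the genes in the opening of the other observations.

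Alternatives were quantile normalization, centring arrays on their median, leaving out the dimmest 25% of genes, adding 32 before log2, the deposited pair ratios, the replicate number as a block, each array left out in turn, a trend or robust prior in eBayes, a threshold of 0.01, and a threshold of 0.05 with at least 2-fold change. After the data were seen, 4 more were added: removing the gene length trend (a loess curve with span 0.5 of each array's deviation from the gene mean on log2 length) using either block alone, and keeping the longest array gene of each set of overlapping ones, which leaves out 88 of the 4997. The fits were tested on simulated data with the wild-type means and limma's moderated variances, in which 200 of 4997 genes changed by 1.5, 2, 4 or 8 times. For the comparison of deletion with wild type, 100% of the changed genes were recovered at each size, and 0.35% of unchanged genes were called. With a length trend added and then removed, 100% were again recovered. In a simulated list test, the 1 shifted list of 10 was called and 0 of the others. The simulated genes varied independently and carried no slide effect, so these rates do not cover correlated genes or a difference between slides. Figures were drawn with matplotlib.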

Results

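Messenger RNA levels were measured in logarithmically growing fission yeast, Schizosaccharomyces pombe, in rich medium at 30 °C, in a wild-type strain and in a strain deleted for red2. Total RNA of each culture was labelled with Cy3 and hybridised to a 1-colour oligonucleotide array that carries 4997 array genes of the 3 chromosomes. Each group had 2 arrays, 4 in all, and each gene had 2 blocks of values per array, which were averaged on the log2 scale. The median deposited intensity was 21231.7 and 21304.1 on the wild-type arrays and 22141.0 and 22158.1 on the deletion arrays. Arrays of the same group correlated across genes with r = 0.9975 for wild type and r = 0.9964 for the deletion, against 0.9338 to 0.9447 between groups. Nothing in the labels says that the arrays of a group came from separate cultures, so p-values measure only the spread between these arrays, which may be technical. The small number of arrays limits the precision.

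The comparison asks how the transcriptome of vegetative cells differs once red2 is absent. The targeted gene could not be looked up, because no table used here ties the name red2 to an array gene. A single array gene was lost in the deletion strain: a serine- and proline-rich protein of unknown function on chromosome I, 2603271 to 2604926, stood at 14.93 and 15.05 on the log2 scale in wild type and at 5.39 and 4.75 in the deletion. The decrease passed the test (limma adjusted p = 6.72e-06), but its size is not given, as the deletion values lie near the bottom of the scale. The next largest decrease among the 4997 genes was -1.82. Of the 4808 genes above 11 on both wild-type arrays, this was the 1 gene below 9 on both deletion arrays, and 0 genes were below 9 on a single deletion array. The label of deletion replicate 2 names red3 in one place and red2 in the others, and red3 is not tied to an array gene here either.

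Deletion of red2 went with raised levels of several genes of meiosis in cells that were growing vegetatively. Within the gene list for meiotic recombination and the chromosome axis, which was fixed before the data were examined, the highest members were rec11, which encodes a meiotic cohesin subunit, and mek1, which encodes a meiotic protein kinase of the recombination checkpoint. The level of rec11 (chromosome III, 1227770 to 1230824) rose by 2.42 ± 0.06 on the log2 scale (SE, 2 arrays per group), a 5.36-fold difference, with limma adjusted p = 7.26e-06. A shorter array feature of the same name, which overlaps the first, rose by 1.57 ± 0.06. The level of mek1 (chromosome I, 5192341 to 5193767) rose 4.53-fold, by 2.18 ± 0.05 on the log2 scale. The recombination genes rec15, rec6 and rec7 rose by 1.15 ± 0.13, 0.81 ± 0.07 and 0.49 ± 0.05. All 6 array features of that list with a symbol, at 5 loci, rose, whether adjusted over all genes or adjusted over the list alone. The list names 18 genes, so most of its members had no symbol and were not tested. The matched features lay above the other genes with a median log2 fold change of 1.36 (limma camera adjusted p = 0.00132). That call was lost with camera's estimated correlation, at adjusted p = 0.409. With the longest feature kept of each overlapping set, adjusted p was 0.00519. The list was not tested without dim genes, since fewer than 3 members were left.

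A wider set was drawn from the array's own descriptions. Of 10 array features described as acting in meiotic recombination, at 9 loci with both features of rec11 among them, 8 rose, 1 fell and 1 did not pass the test. The exceptions were rec14, which fell by 0.23 ± 0.07, and a gene at 1765087 to 1766365 of chromosome I, at 0.03 ± 0.06. The fall of rec14 did not pass without wild_type replicate 2 (limma adjusted p = 0.096), with the length trend removed (0.0999) or with the first block alone (0.182). The median log2 fold change of the 10 features was 0.98 (camera adjusted p = 0.00421), against adjusted p = 0.556 with an estimated correlation. The larger group described as acting in meiosis, sporulation or sexual differentiation had 18 members that rose, 6 that fell and 8 that did not pass, of 32 features at 30 loci, with a median of 0.28 (camera adjusted p = 0.0374, and adjusted p = 0.556 with an estimated correlation). Its highest members besides rec11 were a regulator of premeiotic DNA synthesis (2.37 ± 0.07) and a gene described as upregulated in meiosis on chromosome I, 3791304 to 3791676 (2.22 ± 0.05). Its lowest members were a meiosis II protein (-0.82 ± 0.09) and ste4, a sexual differentiation gene (-0.75 ± 0.09). The call of this wider group ended with quantile normalization (adjusted p = 0.0648), without red2 deletion replicate 2 (0.0766) and with the longest feature kept of each overlapping set (0.106), and leaving out the dimmest 25% of genes ended the call of both groups, with adjusted p = 0.401 for meiosis and sporulation and 0.517 for recombination.

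**Figure D1:**
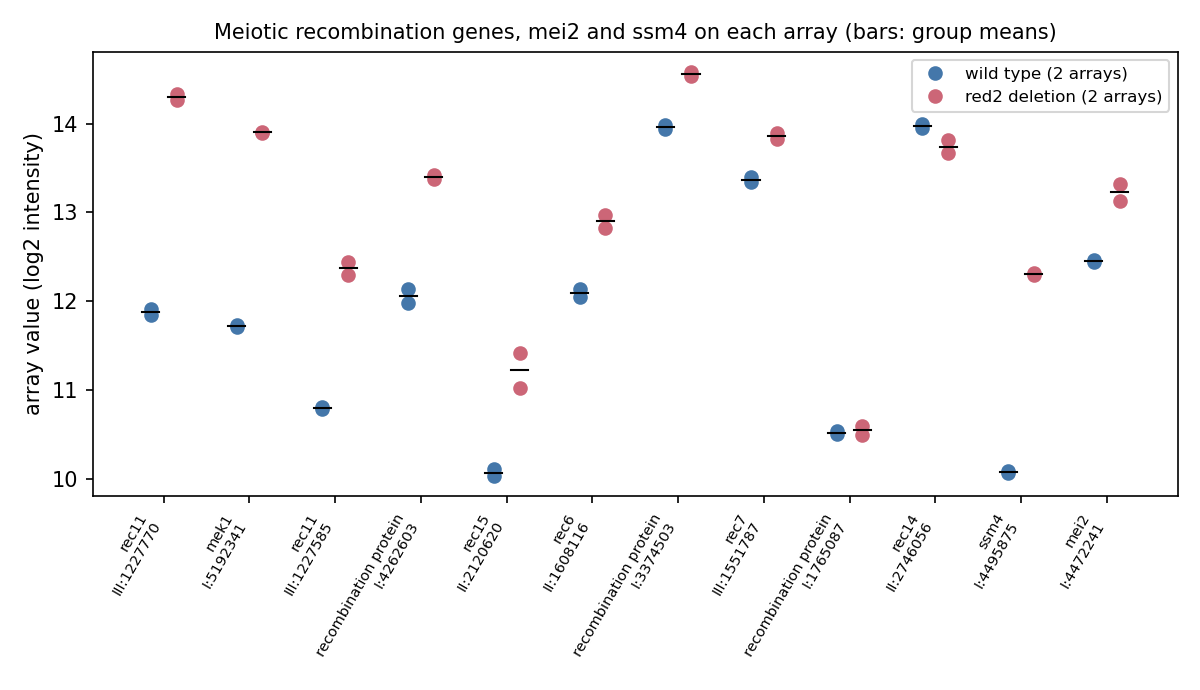
Array values (y axis, log2 intensity) of the 10 array genes described as acting in meiotic recombination and of ssm4 and mei2 (x axis, symbol with chromosome and start), with 1 point per array, blue for wild type and red for the red2 deletion, and a bar at each group mean. The deletion arrays lie above the wild-type arrays for rec11, mek1, rec15, rec6, rec7, ssm4 and mei2, and below them for rec14.

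The genes with a fixed place in the comparison included ssm4 and mei2. The level of ssm4, which encodes a microtubule-associated protein of meiotic nuclear movement, rose 4.71-fold (log2 2.23 ± 0.05, limma adjusted p = 6.95e-06). The level of mei2, an RNA-binding protein needed for the start of meiosis, rose 1.71-fold (log2 0.77 ± 0.07). The genes mei4, rec8, spo5, mcp5, crs1, mmi1, red1, ste11 and pho1 were to be named as well, but their symbols were not tied to array genes. Any of them may still be among the genes given here by description alone. The list of meiotic messages bound by Mmi1, an RNA-binding protein that marks such messages for destruction, could be matched for mek1 and ssm4 alone, which is too few for a test.

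The lists for sporulation, mating, starvation, stress and the G1/S transition were not called, but most of their members had no symbol. The sporulation list had 4 matched features for 20 listed genes, mating 4 for 17 and starvation 5 for 13. Stress had 3 for 17 and G1/S 4 for 12. The unmatched members were not tested, so these results do not speak for the whole lists. In the list for middle meiosis and sporulation, spn5 and meu14 rose, by 0.82 ± 0.07 and 0.55 ± 0.05. The other members stood at 0.25 ± 0.11 for isp3 and 0.03 ± 0.07 for spo6, neither past the threshold in the main fit, and isp3 passed without red2 deletion replicate 1 (log2 0.41, adjusted p = 0.00257) and with the gene length trend removed (log2 0.495, 0.00439). The list was not called (camera adjusted p = 0.169), nor were the mug and meu genes, named for upregulation in meiosis (2 of 4 rose, adjusted p = 0.144). Those 4 included spn5, meu14 and isp3, so the sporulation list and this one overlap. In the mating and pheromone list, mei2, fus1 and ste6 rose and ste4 fell (adjusted p = 0.368), but fus1 and ste6 did not pass with the gene length trend removed (log2 0.08 and 0.03). Of the nitrogen starvation list, 4 of 5 members rose, led by mei2 and isp4 (0.75 ± 0.08), with adjusted p = 0.144. The core stress list had 1 of 3 members that rose (adjusted p = 0.368). Its member hsp9 stood at log2 0.229 without red2 deletion replicate 2, and passed with the length trend removed (log2 0.518). The list also names hsp16, which was not tied to a symbol and so was not tested with it. A gene described as heat shock protein 16 fell by 1.33 ± 0.10 (limma adjusted p = 0.00017), and stood at -1.05 with the length trend removed. Among genes of the G1/S transition, rad21 (0.93 ± 0.10), a mitotic cohesin subunit, and mik1 (0.86 ± 0.07), an inhibitor of mitosis, rose (list adjusted p = 0.635). The other members, cdt1 (-0.17 ± 0.05) and cig2 (-0.17 ± 0.05), fell, but neither passed without wild_type replicate 1 (limma adjusted p = 0.117 and 0.247) or without wild_type replicate 2 (0.148 and 0.0923), nor cig2 without red2_deletion replicate 1 (0.0864) or with the replicate number as a block or the deposited pair ratios (0.0556 in both). With the first block alone cig2 did not pass (0.0835), and with the second neither did (0.534 for cdt1, 0.088 for cig2). These counts were the same adjusted over the list alone. Of 19 genes described as acting in mating or pheromone response, 11 rose, 3 fell and 5 did not pass (adjusted p = 0.12). Those that fell were M-factor precursor 2 (-0.94 ± 0.15), the mating-type polypeptide Mc (-0.59 ± 0.07) and M-factor precursor 3 (-0.45 ± 0.05), of which the last did not pass with the length trend removed (log2 -0.066, limma adjusted p = 0.3). Genes of M cells did not all fall, as M-factor precursor 1 (0.28 ± 0.07) rose past the threshold. The mating-type polypeptide Mi passed as higher too, but its values lie near the bottom of the scale. They were 5.82 and 6.04 in wild type and 6.26 and 6.31 in the deletion, and no size is read from them.

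The strongest increases of all lay outside the recombination genes. A gene that the array describes as a putative GTP cyclohydrolase of riboflavin biosynthesis (chromosome I, 1827631 to 1828950) rose 23.4-fold, by 4.55 ± 0.09 on the log2 scale (limma adjusted p = 6.18e-06). That role was not checked here. A coiled-coil protein similar to the end of a nuclear migration protein (chromosome II, 817773 to 820679) rose 17.2-fold, and a homologue of fork-head transcription factors (chromosome II, 1431572 to 1433125) rose 9.44-fold. A probable uracil phosphoribosyltransferase, an enzyme that salvages uracil, rose 9.32-fold (chromosome I, 1823174 to 1823743). It lies near the GTP cyclohydrolase gene. Other genes described as this enzyme, looked up after the values were seen, differed in direction. They stood at 0.53 ± 0.05 and -0.30 ± 0.06 on the log2 scale, both past the threshold. A WD repeat protein (log2 2.56 ± 0.06) and an RNA-binding protein (log2 2.38 ± 0.06), both on chromosome II, were also among the 12 highest, with rec11 and 5 genes of unknown function.

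Apart from the lost gene, the 12 lowest genes were mostly short. They held a UPF0057 family protein (chromosome II, 807697 to 807849), which fell by 1.82 ± 0.13 on the log2 scale (limma adjusted p = 0.000148). Among them were also a putative oligosaccharyltransferase subunit (-1.61 ± 0.08), a mitochondrial ribosomal protein like L33 (-1.58 ± 0.05) and 1 of the histone H4 genes (-1.55 ± 0.05). The other histone H4 genes stood at -0.23 ± 0.05, past the threshold, and -0.13 ± 0.06, not past it, and turned to 0.092 and 0.196 with the length trend removed. The former did not pass without wild_type replicate 1 (limma adjusted p = 0.0613), and the latter passed with quantile normalization (0.0363), arrays centred on their median (0.0346) or the first block alone (0.044); their signal lies near the top of the scale, and these are near-identical copies whose probes could share signal. The median length was 385.5 bp for the 12 lowest genes, 1113 bp for the 12 highest and 1194 bp for all array genes.

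Genes of the respiratory chain and ATP synthase fell as a group. Of 37 such genes, 24 fell, 3 rose and 10 did not pass the test, with a median log2 fold change of -0.26 (camera adjusted p = 0.000472, and adjusted p = 0.556 with an estimated correlation). The subunit VIIc of cytochrome c oxidase fell 2.83-fold and the subunit VIb by 1.05 ± 0.05 on the log2 scale. With the length trend removed the group kept its direction (median -0.10, adjusted p = 0.0274).

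Other groups moved with gene length, and their calls depended on it. Of 127 cytosolic ribosomal protein genes 50 fell, 4 rose and 73 did not pass (median -0.11, camera adjusted p = 0.000441). With the length trend removed the group turned to a median of 0.11 (adjusted p = 0.0274), with 49 genes higher and 11 lower. Of 29 proteasome genes 15 fell and 4 rose (median -0.15, adjusted p = 0.0369), with adjusted p = 0.285 once the trend was removed. Of 22 nuclear pore genes, which are long, 10 rose and 0 fell (median 0.16, adjusted p = 0.0235), with adjusted p = 0.797 once it was removed. Of 9 core histone genes 5 fell and 0 rose (median -0.23, adjusted p = 0.0374), and the median turned to 0.09 with the trend removed (adjusted p = 0.796). Each of these calls had adjusted p = 0.556 with an estimated correlation. Quantile normalization ended the call of the histones (0.0648), as the first block alone did for the histones (0.0806) and the proteasome (0.069). Leaving out an array ended the call of the histones without wild_type replicate 1 (0.0879), wild_type replicate 2 (0.0521) or red2_deletion replicate 2 (0.117), of the nuclear pore without wild_type replicate 1 (0.0581) and of the proteasome without red2_deletion replicate 2 (0.0766).

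**Figure D2:**
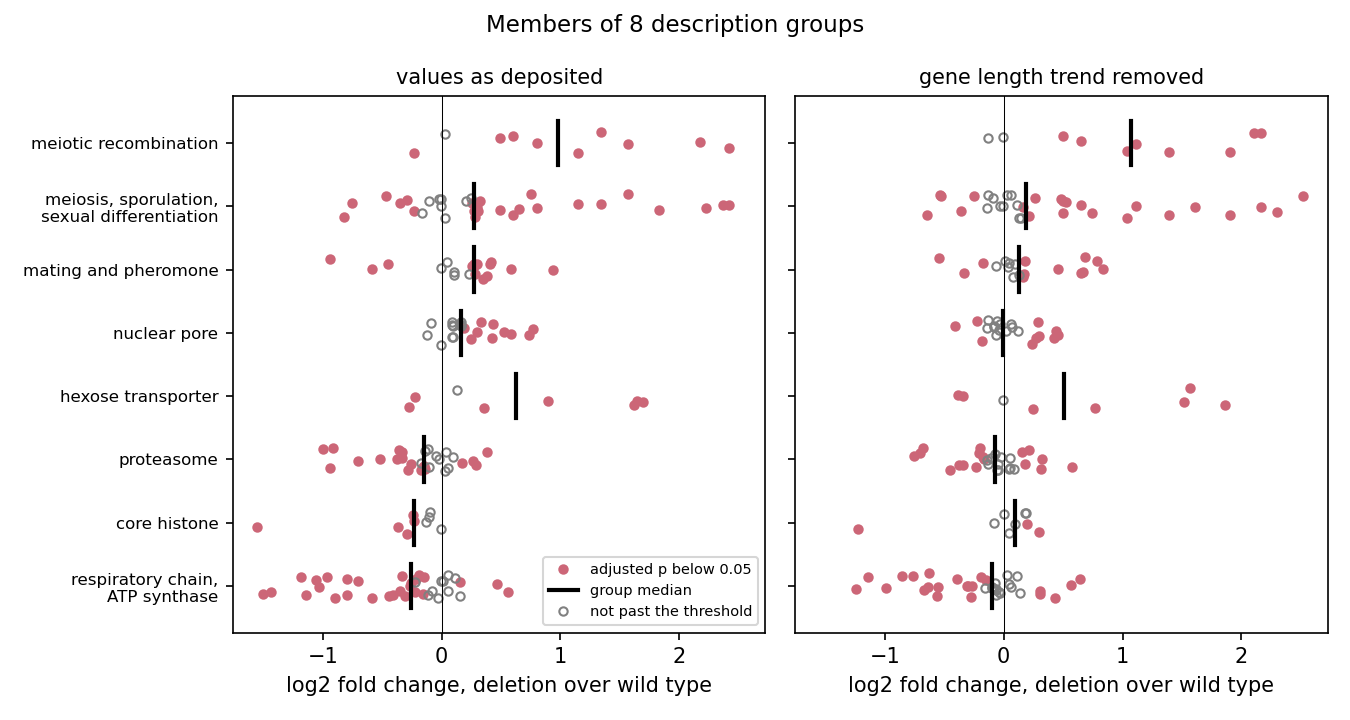
Log2 fold change, red2 deletion over wild type (x axis), of each member of 8 description groups (y axis), from the deposited values on the left and with the gene length trend removed on the right. Filled points passed limma's adjusted p threshold of 0.05, open points did not, and black bars are group medians. The bar of the meiotic recombination group lies at 0.98 on the left and 1.07 on the right, and that of the nuclear pore at 0.16 and -0.01.

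In counts, 1699 of the 4997 genes were higher in the deletion and 1487 were lower (limma, two-sided, Benjamini-Hochberg adjusted p under 0.05). With each array centred on its median the balance turned, to 1478 higher and 1788 lower. Most differences were small, with a median absolute log2 fold change of 0.26. At least 2-fold differences without overlap between the groups were found for 136 genes higher and 127 lower (123 and 157 with arrays centred, 122 and 140 with quantile normalization), and 26 genes were at least 4-fold higher against 1 lower. Groups did not overlap for 4229 genes in either direction, where chance gives 33.3% of genes. Fold change rose with gene length across genes (Spearman rho = 0.445; genes are not independent replicates), from a median of -0.30 in genes up to 300 bp to 0.28 in genes of 3000 to 5000 bp, and 0.218 in the 65 genes above 5000 bp. With that trend removed, 154 genes were at least 2-fold higher, 117 of them shared with the 136, and 50 were at least 2-fold lower, all 50 shared. The array names place the wild-type arrays on 1 slide and the deletion arrays on another, so slide and genotype cannot be told apart.

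**Figure D3:**
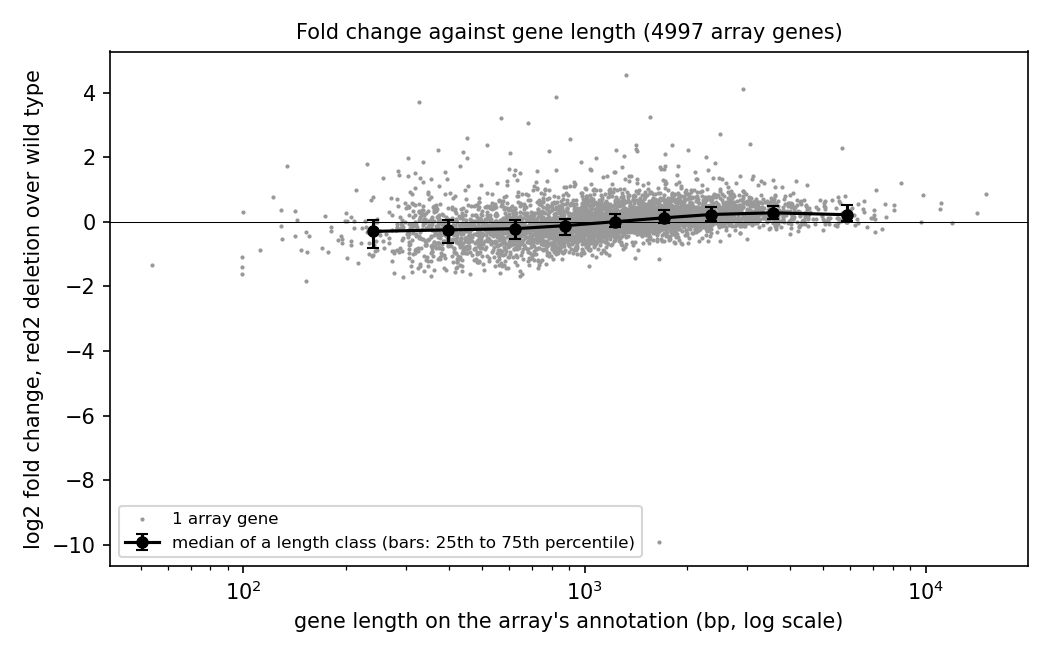
Log2 fold change, red2 deletion over wild type (y axis), against gene length in bp (x axis, log scale) for 4997 array genes, as grey points. Black points are medians of length classes with bars from the 25th to the 75th percentile, and they climb from -0.30 in the shortest class to 0.28 at 3000 to 5000 bp and stand at 0.218 above 5000 bp.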

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

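The removal of the gene length trend, the use of a single block and keeping the longest of overlapping array genes were chosen after the data were seen. The counts of genes higher and lower stayed within 1.5 times of 1699 and 1487 under every alternative but the 2-fold rule, which left 136 and 127. Their balance turned with each array centred on its median, to 1478 higher and 1788 lower. The 2-fold balance turned there too (123 higher, 157 lower), with quantile normalization (122, 140), without red2_deletion replicate 2 (147, 163), with the second block alone (135, 140) and without the dimmest genes. The 2-fold counts, 136 and 127, went to 36 and 44 without the dimmest genes, which removes genes by construction, and the lower count went to 50 with the length trend removed. With each array left out in turn the counts ran from 1424 to 1729 higher and 1216 to 1594 lower. The arm left with a single array is assumed to vary like the other. With the replicate number as a block, 1674 genes were higher and 1466 lower, as with the deposited pair ratios. The replicate numbers did not pair the arrays (r = -0.041 across genes between the deviations of the same numbers), and the block changed no list call but ended that of the gene cig2 (0.0556) and called orotidine 5'-phosphate decarboxylase lower (0.000348). For the 24 genes in the 2 sets of 12, all 361 values under the alternatives kept direction and passed. These genes were chosen as the largest changes past the threshold on the same arrays, so this outcome was close to fixed beforehand. A gene removed by an alternative gave no value there.

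List calls varied more, and where no construction is named the cause was not tested. An estimated correlation ended all calls, at adjusted p = 0.409 for the recombination list and 0.556 for the 7 description groups. Its few degrees of freedom make this outcome likely for any list. The estimates for the nuclear pore (-0.005) and the proteasome (-0.036) lay below the preset 0.01, yet their calls ended too. Those of the other called lists lay above it. The loss of calls alone does not show correlation within the lists. Fry, which tests a list alone and so calls any group that moves, called sporulation at 0.0057, mug and meu genes at 0.000603, mating and pheromone response at 0.0057, nitrogen starvation at 0.00447, core stress at 0.0128 and G1/S genes at 0.00983. Among the description groups it called mating at 0.0101, hexose transporters at 0.0109, amino acid permeases at 0.0112, MFS transporters at 0.00165, iron uptake at 0.0132, tRNA synthetases at 0.0098, oxidoreductases at 0.0111, glucan synthases and septins at 0.00787, wtf genes at 0.0101, pseudogenes at 0.0494 and serine- or threonine-rich proteins at 0.012, and turned exosome and ribonuclease genes upward at 0.0199. Quantile normalization left meiosis and sporulation and the histones each at 0.0648. Without the dimmest genes, meiosis and sporulation was at 0.401 and recombination at 0.517, with fewer members by construction, and very hypothetical proteins were called lower at 0.00876; lists left with fewer than 3 members gave no value. With the length trend removed, ribosomal proteins turned upward at 0.0274 and histones at 0.796, the nuclear pore stood at 0.797 and the proteasome at 0.285, and oxidoreductases were called higher at 0.0274. Keeping the longest of overlapping array genes left meiosis and sporulation at 0.106. The first block alone left histones at 0.0806 and the proteasome at 0.069. Without an array the adjusted p ran from 0.014 to 0.0766 for meiosis and sporulation, 0.0198 to 0.117 for histones, 0.0182 to 0.0581 for the nuclear pore, 0.0305 to 0.0766 for the proteasome, 0.0392 to 0.163 for hexose transporters and 0.0352 to 0.106 for iron uptake. With the length trend removed 5 named genes turned: gal10 to -0.028, histone H2A-beta to 0.004, histone H2A-alpha to 0.046 and a histone H4 gene to 0.092, none past the threshold, and another histone H4 gene to 0.196, past it. Signal over background was not given, so dim genes have no stated floor.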

Other observations

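The single genes named next were chosen after their values were seen. The tests of the length trend, of a mixture of cells and of lost genes, and the removal of the length trend itself, were chosen after the data were seen, with the bounds for the recombination genes written before that 1 value was computed.

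Genes described as parts of dynein, a microtubule motor, were not tested as a group and differed in direction. The dynein heavy chain rose by 2.30 ± 0.06 on the log2 scale (limma adjusted p = 1.01e-05), the intermediate chain by 2.09 ± 0.12, and centractin, an actin-like protein of dynactin, by 1.71 ± 0.06. The intermediate chain shares its start with the WD repeat feature named among the 12 highest genes. A dynein light chain-like gene fell by 1.06 ± 0.06 and another light chain stood at 0.06 ± 0.05. The latter passed with the length trend removed (0.325) and with the second block alone (0.182). A gene described as cohesin (chromosome II, 2528016 to 2529888) rose by 1.72 ± 0.05.

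Neither the hexose transporters nor the iron uptake genes were called as a group, and single genes moved. Fructose-1,6-bisphosphatase, an enzyme of gluconeogenesis, rose by 1.64 ± 0.08 and a gene described as isocitrate lyase by 0.92 ± 0.05. Of 8 hexose or glucose transporter genes, 5 rose and 2 fell (camera adjusted p = 0.122, between 0.0392 and 0.163 without an array), with the highest at 1.70 ± 0.11. A multicopper oxidase rose by 1.46 ± 0.05, and all 3 genes described as iron reductase or permease rose (adjusted p = 0.0827, between 0.0352 and 0.106 without an array). The orotidine 5'-phosphate decarboxylase gene, an enzyme of uracil synthesis, was near the bottom of the scale on all 4 arrays, at 5.84 and 4.97 in wild type and 5.07 and 4.45 in the deletion. It did not pass in the main fit (limma adjusted p = 0.12) but was called lower under 6 alternatives, with adjusted p from 0.000257 to 0.0486, and no size is read from values so near the floor. The gene next to the lost gene, at 2601640 to 2602875 of chromosome I, rose by 2.22 ± 0.05, and the neighbour on the other side stood at -0.11 ± 0.06, which passed only without red2 deletion replicate 2 (-0.182).

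Fold change followed gene length between the groups, with a slope of 0.19 on the log2 scale per doubling of length. Compression near the top of the scale is argued against, since among genes with means of 12 to 14 the rho with length was 0.473, not lower. A length bias between arrays, from RNA, labelling or hybridisation, is a possible explanation, as the 2 deletion arrays differed along length too (rho = 0.276), though their slope was only 0.03 and the wild-type arrays gave rho = -0.045. Whether red2 deletion itself makes the trend cannot be told apart from slide, because 0 slides held arrays of both genotypes.

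The rise of the meiotic recombination genes was set against that trend and against cells in conjugation, meiosis and sporulation within the culture. With the length trend removed, the median log2 fold change of the 10 described features was 1.074, against 0.98 before. Removal could move it little, as their median length of 1127.5 bp is near the 1194 bp of all array genes. Genes of 1000 to 1500 bp had a median of 0.001. These values argue against the trend as the cause of the group's median rise. Of 20 array features of the meiosis and mating groups with a wild-type mean under 12, 13 (65%) had a 95% upper limit under 1 while 6 had a lower limit over 1, among them rec11 and mek1; overlapping features joined, these were 13 of 18 loci (72.2%) against 4. Of the 13, 5 rose past the threshold, by up to 0.55, 3 fell and 5 did not pass. These counts rest on values that carry the length trend. With it removed, M-factor precursor 1 (0.663), p-factor precursor (0.647) and meu14 (0.610) rose past the threshold. So did isp3 (0.495) and a 21 kd protein inducing meiosis (0.478). Mi also passed as higher, but its values lie near the bottom of the scale and no size is read from them. M-factor precursor 2 (-0.544) and Mc (-0.338) fell past it, and the others did not pass. A mixture that raised all of them would leave no falls, but a mixture as such is not excluded. Cells stopped early in meiosis, which would not raise late genes, and a difference between the slides or strains other than red2 stay open, so a response to red2 loss is a hypothesis.

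The array gene that fell to the floor of the scale bears on the label that names red3. If deletion replicate 2 lacked another gene in place of the one lost in replicate 1, genes lost on a single deletion array would be seen; there were 0, and 1 gene was lost on both. A gene that is not on the array, or is dim in wild type, would not be seen by this test. Whether the lost gene is red2 was not settled, as no table used here names it.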
